A study of Caenorhabditis elegans with 2 samples.

How the data were processed

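RNA 3' ends were sequenced from 2 Caenorhabditis elegans libraries, 1 of input nuclei from mixed tissues and 1 of nuclei collected by fluorescence-activated sorting, both of strain JM149. Per the labels, liquid cultures of mixed stages were grown at 25 °C and strained to enrich adults, and RNA was reverse transcribed from an oligo(dT) primer of 24 T, amplified as antisense RNA, ligated to an adapter and amplified by 12 cycles of PCR. The molecule label differs between the libraries (total RNA for input, nuclear RNA for sorted), so it cannot be separated from the comparison. The labels used here do not say which cells carried the fluorescent mark, and the series title names intestinal expression and alternative polyadenylation as the subject.

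The authors deposited, for each library, counts of reads per position and strand, as whole numbers that are not scaled. The other deposited column used here is the position itself, with start and end equal in every line, and whether it is counted from 0 or from 1 is not stated. TopHat is named in the submitters' processing notes with no version. The genome build, read filters and the handling of multiply mapped or A-rich reads are not given in the sources used here.

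The build was examined by comparing positions with at least 10 reads with annotated 3' ends of WBcel235 gene models in 203 windows of 0.5 Mb. The commonest offset ranged from -7 nt to 120 nt in 200 windows and was 4610 or 4611 nt in the last 3 windows of chromosome V, so the files use another build. Gene models were used only in the 41 windows (20.5 Mb) whose offset was at most 5 nt in size, 16 of them on I, 4 on II, 2 on III, 8 on IV, 6 on V and 5 on X. On each chromosome these windows lay toward its start. No coordinate was converted. A position kept its gene only where shifts of 10 nt to either side gave the same gene. In these windows a median of 43.5% of the positions compared lay within 3 nt of the window's offset, against 0.189% at an average offset. Positions printed here are those of the files. Genes elsewhere were not analysed by name, and among the 4 check genes fixed beforehand (elt-2, ges-1, unc-54 and rol-6) only ges-1 lay in the windows.

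Reads were summed per protein-coding gene on its strand, over its span plus 300 nt downstream, and scaled to RPM, reads per 1000000 gene-assigned reads. Genes needed at least 20 reads over both libraries. The log2 ratio of sorted over input was taken with 0.5 reads added to each library, and the ratio itself with an exact 95% interval from the binomial distribution of a gene's reads between the libraries. A gene was called higher or lower when the bound nearest 1 passed 4-fold, with 2-fold beside it. With 1 library per group no test between groups was possible and no replicate check exists. Intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 reads, which is 1.73 RPM in input and 3.65 in sorted nuclei. Each of 27 gene lists fixed before the data were examined was summarised by the median log2 ratio of its measured members. For the 20 lists with at least 3 such members, the percentile of that median among 10000 random lists matched on reads in 20 bins was taken. Lists marked as prefix take every gene symbol that starts with the family's letters, and members can stand in several lists.

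Within genes, 3' ends were clustered by taking the position with the most reads and every free position within 24 nt. A site was kept with at least 5% of the gene's reads in either library, and genes needed at least 20 reads in each library. A gene was called shifted when a site's share differed by at least 20 percentage points and the exact (Clopper-Pearson) 95% intervals did not overlap, and the direction is that of the mean read position. The number that counting error alone gives was taken from 100 draws of both libraries from pooled shares. Sites per gene were counted with both libraries thinned to 822109 gene-assigned reads. The same clustering was run along all nuclear chromosomes without gene models, scaled to all nuclear reads. No sequence of the files' build was used here, so the planned removal of possible internal priming (an oligo(dT) primer binding A-rich stretches inside a transcript) and the planned sequence comparison around polyA sites were not run.

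Genes named were fixed by rule: the 12 with the highest lower bound and the 12 with the lowest upper bound of the ratio, the 10 with the most sorted and the 5 with the most input reads, up to 4 members with the most reads in each list, the check genes, and the 6 genes with the largest gap between share intervals in each direction. Further members of lists, the clusters along the genome and the families in the closing section were chosen after their values were seen. Alternatives covered scaling (TMM of edgeR 4.0.16, median of ratios of DESeq2 1.42.0, all reads), positions counted once, read minimums, gene extension, pseudocount, clustering distance, share thresholds and thinning.

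The rules were tested on simulated data. Of 50 genes simulated 8-fold higher 50 were called, of 50 simulated 8-fold lower 18 were called, and of 1809 unchanged genes 0 were called. Of 50 genes given a 40-point site shift 47 were called, and of 679 unchanged genes 4 were. The simulated reads were drawn independently, as the intervals assume. These rates therefore leave out variation from amplification and between libraries, and are not false-call rates of the real data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.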

Results

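3' end reads were counted in 2 libraries, input nuclei from mixed tissues and nuclei collected by fluorescence-activated sorting, with 1 library per group and therefore no replicates. The input library held 9243831 reads at 215104 positions and the sorted library 4709432 reads at 165811 positions. The 88380 positions seen in both held 97.6% of input and 97.2% of sorted reads. Mitochondrial reads were 0.255% of the input and 0.146% of the sorted library. Gene models could be used in 20.5 Mb of the genome, which held 1767430 input and 852083 sorted reads, of which 1734170 and 822109 fell in protein-coding genes. Of these gene reads, 89.2% in input and 87.01% in sorted nuclei lay within 24 nt of an annotated 3' end.

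The first comparison asked which transcripts differed in level between sorted and input nuclei, the series being titled for intestinal expression. Of 8 measured digestive and structural genes of the intestine, 5 were at least 2-fold higher in sorted nuclei, or 4 under TMM or median-of-ratios scaling, and of 3 intestinal transcription factors 1 was, or 0 under these scalings. The gap-junction gene inx-16 was 8.11-fold higher (95% interval 7.21 to 9.15), its neighbour inx-15, another innexin, 15.9-fold (12.5 to 20.6), and the gut esterase gene ges-1 3.46-fold (3.29 to 3.64). Among abundant input genes, the adult cuticle collagen col-19 stood at 0.228 of its input level (0.219 to 0.236), and perm-4, needed for the eggshell's permeability barrier, at 0.325 (0.321 to 0.330). Of 2009 genes measured, 106 (5.28%) were at least 4-fold higher in sorted nuclei and 4 were at least 4-fold lower. At 2-fold, 315 were higher, 72 lower and 1622 neither.

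The genes with the highest lower bounds were mostly rare in input nuclei. F31F4.1 had 5 input and 129 sorted reads, a ratio of 54.4 (22.7 to 170). Y46C8AM.1, the most abundant of them, went from 110 to 2728 RPM (reads per 1000000 gene-assigned reads), a ratio of 24.9 (21.5 to 29.03). The C-type lectin gene clec-84 was 20.8-fold higher (14.7 to 30.3) and pals-23 17.6-fold (14.9 to 20.9). The MATH-domain genes math-3, math-41 and math-16 were 49.2-fold (16.16 to 244), 17.8-fold (11.9 to 27.9) and 29.5-fold higher (12.1 to 93.8), and the F-box gene fbxa-59 16.7-fold (12.2 to 23.4). C26C6.10 was 34.3-fold higher (12.8 to 130), and Y69A2AR.51, with 1 input read, 88.6-fold (15.1 to 3582). ZK355.3 had 0 input and 28 sorted reads, with a lower bound of 14.98 for its ratio.

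At the other end, the 4 genes at least 4-fold lower were col-19, R57.2 at 0.115 (0.0659 to 0.186), nab-1, which encodes neurabin, at 0.133 (0.0748 to 0.220), and W03D8.5 at 0.123 (0.0887 to 0.167). In W03D8.5, 700 of the 754 input reads lay at a position inside the coding sequence. Its call rests on that position, since 54 input and 23 sorted reads lay at its site past the stop codon. Among other lower genes were the nonmuscle myosin gene nmy-2 at 0.257 (0.230 to 0.287), the sperm chromatin gene spch-2 at 0.259 (0.224 to 0.297) and K10C9.7 at 0.246 (0.196 to 0.307). C50F2.2, nep-2 and Y50D4C.3 stood at 0.133, 0.113 and 0.168, with 8, 4 and 12 sorted reads. The RNA helicase gene ddx-10 had 48 input reads and 1 sorted read, a ratio of 0.0439 (0.00109 to 0.257). With 27 input and 0 sorted reads, ndua-12 had an upper bound of 0.309 for its ratio. The genes with the most sorted reads, rla-1 and rpl-24.1, encode ribosomal proteins and stood at 1.30 (1.29 to 1.31) and 0.951 (0.942 to 0.959) of the input level. In input nuclei perm-4 was second to rpl-24.1, with 84246 RPM.

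**Figure D1:**
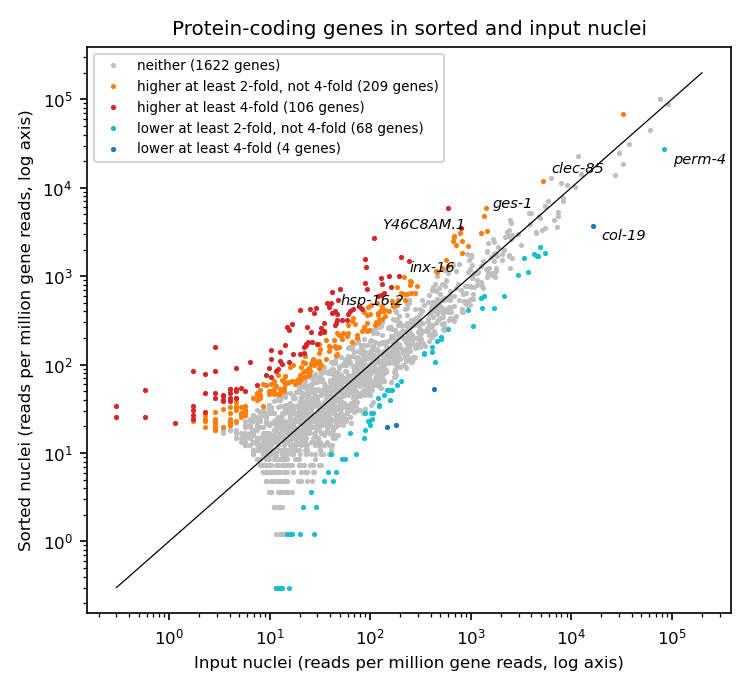
RPM of 2009 protein-coding genes in input nuclei (x, log axis) and sorted nuclei (y, log axis), 1 library each; the line marks equal levels, colours give the calls, and genes with no read in a library are drawn at the lowest value of that axis. The 106 genes at least 4-fold higher in sorted nuclei lie mostly at low input levels, and of the 4 lower genes col-19 is the most abundant.

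The split between higher and lower depended on scaling and on what was counted. TMM and median-of-ratios scaling moved every log2 ratio by -0.24 and -0.23. TMM gave 77 higher and 7 lower genes at 4-fold, and 12.2% of genes higher and 6.17% lower at 2-fold, against 15.7% and 3.58% with total gene reads. Without the 300 nt downstream extension 49 of 1057 measured genes were higher and 8 lower. Counting each position once left 0 of 1051 measured genes of either kind at 4-fold. This setting caps each position at 1 read per library and so limits the ratio a gene can reach, so it does not decide the split.

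Among the lists fixed beforehand, the 8 measured intestinal digestive and structural genes had a median log2 ratio of 1.50, at percentile 99.7 of matched random lists, with 5 at least 2-fold higher and 0 lower. Besides inx-16 and ges-1 these were haf-4 at 4.24 (3.29 to 5.49) and haf-9 at 4.04 (2.38 to 7.001), transporters of gut granules, and the intermediate filament gene ifc-2 at 2.32 (2.17 to 2.49), whose call ended under TMM and median of ratios. With each position counted once, which limits the ratio a gene can reach, 0 of 6 were called. The protease gene cpr-5 had a ratio of 1.13 (1.09 to 1.17), a direction that turned under TMM and median-of-ratios scaling. The 3 measured intestinal transcription factors had a median of 1.40 (percentile 90.7), with nhr-86 called at 5.73 (2.305 to 16.12), though not under TMM or median of ratios, and ratios of 2.44 for zip-2 and 2.65 for nhr-80, not called. The 5 immune effectors had a median of 1.18 (percentile 96.8): clec-85 at 2.26 (2.196 to 2.33), dod-19 at 3.04 (2.84 to 3.25) and clec-67 at 4.64 (3.85 to 5.60) were called, clec-85 not under TMM or median of ratios, and the lysozyme genes ilys-3 at 2.21 and lys-7 at 1.16 were not. Of 4 lipid metabolism genes (median 0.82, percentile 79.7), the lipid-binding protein gene lbp-6 at 2.44 (2.02 to 2.95) and the lipase gene lipl-3 at 2.71 (2.14 to 3.44) were called, both only with total gene reads as the scale, while lipl-5 stood at 1.28 and acdh-1 at 0.422. None of the vitellogenin, detoxification, major sperm protein or histone lists had a measured member in the windows.

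Gene families were fixed by prefix as well. Nuclear hormone receptors, a class of transcription factors expanded in this worm, had a median log2 ratio of 1.84 over 31 measured genes (percentile 100), with 15 at least 2-fold higher and 0 lower, or 10 higher under TMM and median of ratios. Among them nhr-88 stood at 11.6 (7.57 to 18.6) and nhr-122 at 3.65 (2.68 to 5.01). For the others of most reads, nhr-98 and nhr-15, ratios were 2.49 and 1.29, not called. Most of the 31 receptors lay on chromosome V, many of them close together. The random lists were matched on reads and not on location, so the percentile counts such neighbours as separate genes. C-type lectins, proteins with a carbohydrate-binding fold, had a median of 1.29 over 24 genes (percentile 100), with 12 higher and 0 lower, or 8 higher under TMM and median of ratios. Among them clec-83 stood at 4.32 (4.05 to 4.61) and clec-170, whose call ended under both, at 2.38 (2.17 to 2.60). The abundant clec-80 stood at 1.36 and was not called. Several of the lectin genes likewise lay close together, on IV. UDP-glucuronosyltransferases, enzymes of detoxification, had a median of 1.78 over 7 genes (percentile 99.1) with 4 higher, or 3 under TMM and median of ratios, including ugt-46 at 4.50 (3.97 to 5.10) and ugt-31 at 2.93 (2.48 to 3.47). The 5 cytochrome P450 genes had a median of 1.76 (percentile 97.2), with 3 called, including cyp-29A3 at 3.22 (2.71 to 3.84). With each position counted once, only 5 receptors and 3 UDP-glucuronosyltransferases were still measured. Their medians fell inside the random range, at percentiles 94.1 and 95.6.

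Markers of other tissues gave different values. Collagens had a median log2 ratio of -0.85 over 23 genes (percentile 0.02), with 6 at least 2-fold lower and 0 higher, or 8 lower under TMM and median of ratios. After col-19, the abundant col-101, col-103 and col-106 stood at 0.435 (0.413 to 0.458), 0.359 (0.339 to 0.380) and 0.305 (0.284 to 0.326). The 10 hypodermis and cuticle genes, col-19 among them, had a median of -0.44 (percentile 7.2), below the random range only with a minimum of 50 reads or with each position counted once, with 2 lower, or 4 under TMM and median of ratios. Of these dpy-5 at 0.388 (0.313 to 0.476) was called, dpy-9 at 0.485 was called only under TMM and median of ratios, and dpy-14 stood at 0.784. Germ line and oocyte genes had a median of -0.71 over 10 genes (percentile 1.16). The RNA-binding protein genes mex-3 at 0.370 (0.349 to 0.392) and wago-1 at 0.429 (0.368 to 0.498) were called lower, and gld-1, a translational repressor of the germ line, was called higher at 3.39 (2.54 to 4.55). In this list perm-2, deps-1 and cpg-3 stood at 0.501, 0.736 and 0.854 and were not called, and under TMM and median of ratios 4 genes, perm-2 among them, were lower. The 3 pharynx genes had a median of -1.17 (percentile 0.63), which lay inside the random range with each position counted once. Of these phat-2 at 0.445 (0.395 to 0.4996) was called, and the muscle genes myo-1 and tnt-4 stood at 0.626 and 0.386. Sperm genes had a median of -1.04 over 3 (percentile 3.60), with gsp-4 at 0.160 (0.0502 to 0.392) called and its close paralog gsp-3 at 0.720.

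The median of body wall muscle genes lay inside the random range, at -0.10 over 9 genes (percentile 35.6), and 0 were called. The troponin C gene pat-10 stood at 1.06, paramyosin (unc-15) at 0.930 and cpn-3 at 0.645. Members ran from unc-89 at 0.452 (0.287 to 0.689) to unc-60 at 1.73 (1.44 to 2.08). Only 2 neuronal genes were measured, unc-13 at 1.27 (0.700 to 2.24) and nlp-12 at 1.61 (0.721 to 3.53). The measured gonad sheath and coelomocyte genes, lim-7 and lgc-26, stood at 0.385 (0.241 to 0.593) and 0.410 (0.346 to 0.484). The small heat shock protein genes hsp-16.2 and hsp-16.41, which are similar in sequence, were 9.02-fold (6.97 to 11.8) and 11.3-fold higher (5.27 to 27.9).

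The remaining lists lay within the random range. Cytosolic ribosomal protein genes had a median of -0.073 over 19 (percentile 48.2), with rps-17 called higher at 2.13 (2.11 to 2.16) and rps-24 at 0.743. Under TMM and median of ratios the rps-17 call ended and rpl-17, at 0.496, was called lower. Nuclear genes of the respiratory chain had a median of -0.65 over 7 (percentile 3.92, 0 called), with cox-6C at 1.14 and ucr-2.3 at 0.633. Proteasome subunits had a median of -0.41 over 6 (percentile 19.9), mitochondrial ribosomal proteins of -0.0034 over 8 (percentile 28.1) and neuropeptide genes of 0.30 over 7 (percentile 62.5), with 0 called in each. Vacuolar ATPase subunits had a median of 0.41 over 6 (percentile 74.0), with 1 called, vha-3 at 0.134 (0.0422 to 0.325).

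**Figure D2:**
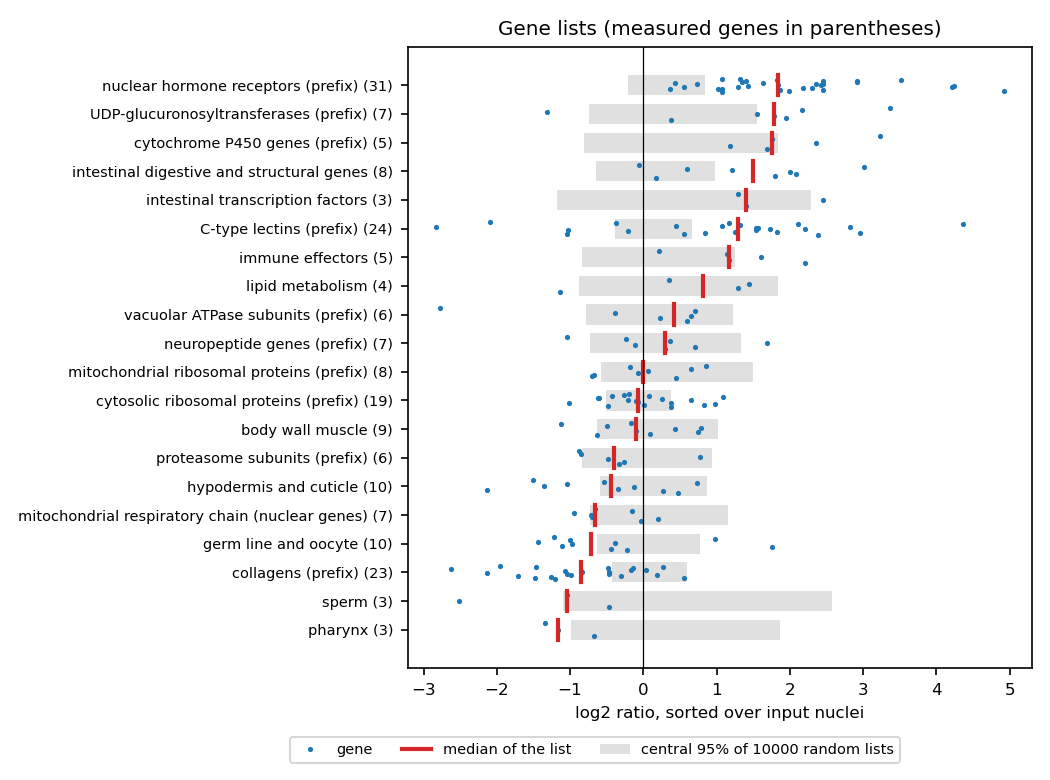
Log2 ratio of sorted over input nuclei for the measured genes of the 20 lists with at least 3 of them (points), the list median (red line) and the central 95% of medians of 10000 matched random lists (grey), 1 library per group. The medians of nuclear hormone receptors (1.84), C-type lectins (1.29), UDP-glucuronosyltransferases (1.78) and intestinal digestive and structural genes (1.50) lie above the grey range, and those of collagens (-0.85), germ line and oocyte (-0.71) and pharynx (-1.17) below it.

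Without gene models, the same comparison covered all nuclear chromosomes. Of 15049 clusters of 3' ends with at least 20 reads, 982 (6.53%) were at least 4-fold higher in sorted nuclei and 164 (1.09%) at least 4-fold lower. The cluster with the most sorted reads, at position 12429046 of chromosome III on the forward strand, went from 12007 to 65698 reads per 1000000 nuclear reads. The share of reads on the X chromosome was 9.61% (9.59 to 9.63) in input and 11.6% (11.6 to 11.7) in sorted nuclei, and on V it was 15.132% and 16.504%. It was larger in sorted nuclei on III as well (22.5% and 24.8%) and smaller on IV (20.8% and 17.7%), I (20.0% and 17.6%) and II (12.0% and 11.7%). Without the 100 largest clusters, a restriction chosen after the data were seen, III went from 17.5% to 15.7% and IV stayed at 17.9%, while V and X kept the larger share in sorted nuclei. Counting each position once, which limits the ratio a cluster can reach, left 0 of 2827 clusters past 4-fold in either direction.

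The second comparison asked whether genes used different polyA sites in sorted nuclei. With all sites kept, more genes shifted toward the proximal than the distal end. This proximal majority was lost with only sites past the stop codon (33 distal against 25 proximal) and with sites in introns left out (48 against 37). Neither split was tested, so they give no distal direction. With only sites near annotated ends 6 of 66 genes shifted (4 distal, 2 proximal). With each position counted once 4 of 210 did, all distal. Both numbers are too small to give a direction. In rpn-8, a proteasome subunit gene, an intronic site at position 4176144 of chromosome I held 2.51% (1.83 to 3.36) of input reads and 44.5% (41.9 to 47.1) of sorted reads, while the site beyond the annotated end, at 4177272, went from 87.5% (85.9 to 89.01) to 47.9% (45.3 to 50.5). Of 1323 genes with at least 20 reads in each library, 729 (55.1%) had 2 or more kept sites, and of these 125 (17.1%) had a shifted site, 77 toward the proximal and 48 toward the distal end. Counting error alone gave a mean of 2.17 shifted genes and at most 8 in 100 draws.

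Intronic sites also gained share in fmo-5, a flavin-containing monooxygenase gene, where the site at 900466 on chromosome V rose from 12.8% (4.30 to 27.4) to 68.3% (58.4 to 77.1). In the phosphatase gene ptpn-22 the intronic site at 1730088 on IV went from 9.26% (3.08 to 20.3) to 59.6% (50.99 to 67.7), and in Y54E10A.10 that at 3174526 on I from 4.67% (1.90 to 9.38) to 49.7% (41.7 to 57.7), while another intronic site of this gene, at 3175275, fell from 47.3% (39.1 to 55.6) to 14.9% (9.79 to 21.4). R12E2.13, which ends opposite rpn-8 on the other strand, had 6.09% (2.48 to 12.1) of input and 51.7% (43.3 to 60.0) of sorted reads at an intronic site at 4178220. Y41D4A.4 went from 64.1% (55.6 to 72.0) to 14.3% (6.75 to 25.4) at its site beyond the annotated end, with no intronic site kept, while a coding-sequence site rose from 10.6% (6.03 to 16.8) to 34.9% (23.3 to 47.97). Of the 35 shifted sites in introns, 29 had the larger share in sorted nuclei, against 46 of the 99 in exons past the stop codon, 11 of 33 beyond the annotated end and 5 of 18 in coding sequence.

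Each of the genes with the largest distal shifts lost share at a site upstream of another, though not at every upstream site. In bet-1 an intronic site, at 4533470 on I, rose from 2.02% (0.658 to 4.64) to 17.6% (9.47 to 28.8), upstream of the site that fell. In bet-1, a bromodomain protein gene, a site in the coding sequence fell from 71.4% (65.3 to 76.9) to 10.3% (4.24 to 20.1) of reads, and in W03D8.5 another such site fell from 92.8% (90.8 to 94.6) to 47.7% (32.5 to 63.3). The last site of clec-84, at 2845601 on IV, rose from 42.9% (26.3 to 60.6) of 35 reads to 86.1% (82.0 to 89.6) of 345. That of Y71F9B.9, at 2759024 on I, went from 36.7% (23.4 to 51.7) to 89.01% (80.7 to 94.6). In C09D4.2 the shift was between close sites, the proximal at 5493211 on I falling from 51.25% (43.2 to 59.2) to 7.84% (2.18 to 18.9), and in Y54G2A.11 the site at 2765911 on IV fell from 48.4% (37.9 to 58.99) to 9.64% (4.25 to 18.1).

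With only sites past the stop codon, a restriction chosen after the data were seen, 514 genes had several sites. Of these, 25 shifted toward the proximal and 33 toward the distal end, so the proximal majority was lost. It was lost also with sites in introns left out, likewise chosen after the data were seen, with 37 proximal and 48 distal shifts. Neither split was tested, so no distal direction is drawn from them. With each position counted once, 4 genes shifted distally and 0 proximally. Possible internal priming was not removed.

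**Figure D3:**
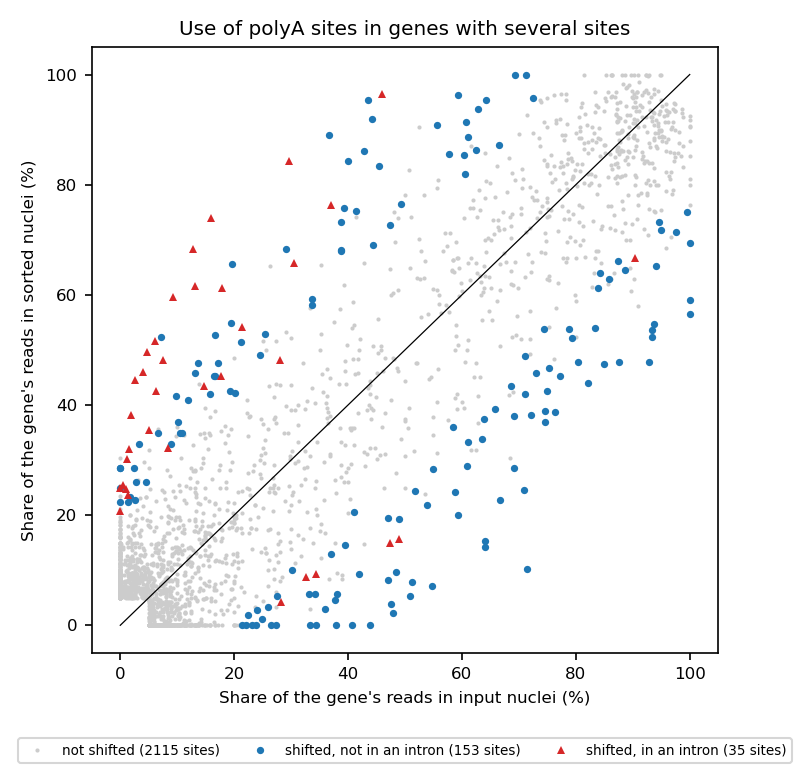
Share of the gene's reads at each of 2303 kept polyA sites in input nuclei (x, %) and sorted nuclei (y, %), 1 library each; the line marks equal shares and colours give sites whose share differed by at least 20 percentage points with intervals that did not overlap. Of the 35 shifted sites in introns (red), 29 lie above the line.

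Shifted genes were found at all levels of expression change. Of the genes with several sites, 23.01% (15.6 to 31.9) of those at least 2-fold higher in sorted nuclei had a shifted site, 26 genes, as did 4 of 17 lower (23.5%, 6.81 to 49.9) and 95 of 599 neither (15.9%, 13.03 to 19.04), and these intervals overlap. The last comparison asked how many polyA sites a gene used. With both libraries at 822109 gene reads, 43.9% (41.2 to 46.7) of 1286 genes in input and 50.0% (47.4 to 52.6) of 1432 genes in sorted nuclei had 2 or more sites. Without thinning the input value was 49.6%, from 1734170 gene reads, and the number of sites found depends on depth. The genes counted differ between the libraries, since each needed 20 reads in the library itself. Sites in introns and coding sequence were counted too, with possible internal priming not removed. The comparison was not repeated without them.

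**Figure D4:**
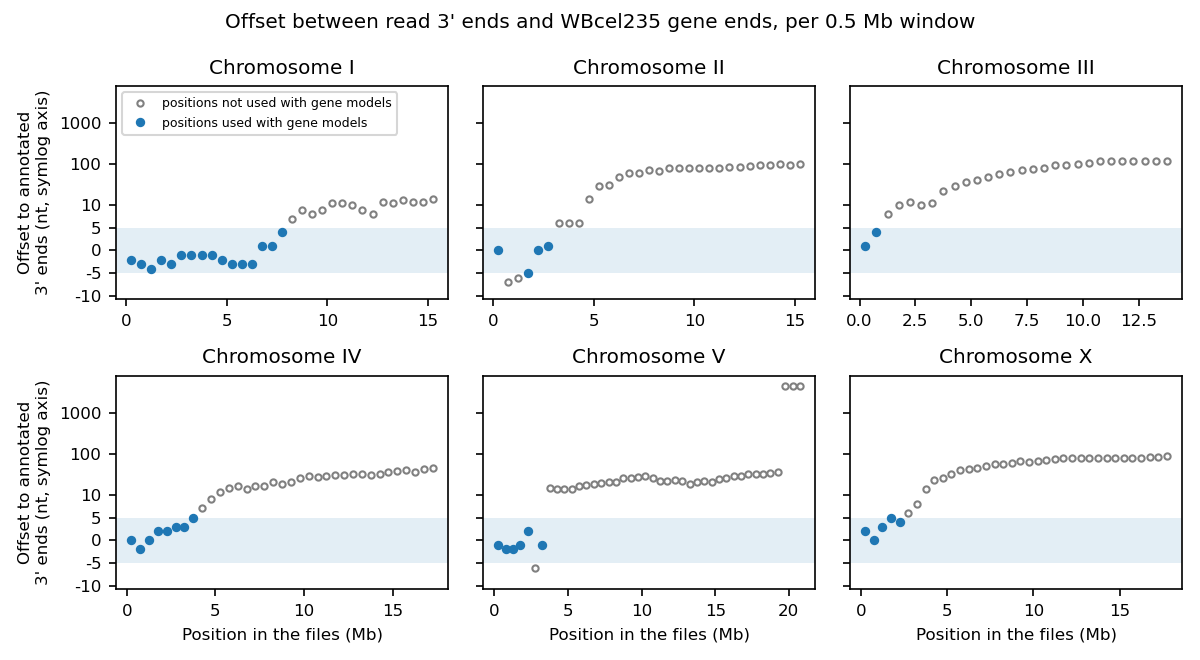
Commonest offset in nt between read 3' ends and annotated WBcel235 3' ends (y, symmetric log axis) along each chromosome (x, Mb in the files), in 203 windows of 0.5 Mb. The 41 windows within 5 nt (filled, shaded band) were used with gene models, and the last 3 windows of V lie at 4610 or 4611 nt.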

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

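These values were looked at because they lie outside the protein-coding genes that the comparisons use. In the windows with gene models, 207 clusters of 3' ends with at least 20 reads lay outside protein-coding genes, and 45 of them were at least 4-fold higher in sorted nuclei, against 0 at least 4-fold lower. The cluster with the highest lower bound, on the reverse strand at position 3821674 of chromosome I, had 6 input and 297 sorted reads, a ratio of 97.1 (44.1 to 267) per nuclear read. Another, on the forward strand at 2106948 of chromosome II, had 11 input and 427 sorted reads, a ratio of 76.1 (42.1 to 154). Reads outside genes were 1.09% of the window reads in input and 2.63% in sorted nuclei, and reads antisense to genes 0.392% and 0.720%.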

How the results depend on the processing

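Alternatives that restrict reads or sites to places past the stop codon, outside introns, near annotated ends or in closer windows, that thin the input library, or that concern the clusters along the genome were chosen after the data were seen; the others were fixed before the data were examined. The alternatives that remove possible internal priming and those on the sequence around polyA sites were not run, because no sequence of the files' build was used. No paired analysis was possible because each group has 1 library. For the counts below, the cause was not tested except where the alternative itself lowers the number counted. Counting each position once leaves few counts per gene and gave 0 higher and 0 lower genes at 4-fold, 0.571% and 0% of genes at 2-fold, list medians of -0.34 for collagens, 0.54 for nuclear hormone receptors and 0.44 for C-type lectins, 4 distal and 0 proximal shifts, and for clusters along the genome 0 and 0 at 4-fold and 0 and 3 at 2-fold. The 2-fold calls are given as a share of the genes measured, a unit that replaced counts after the values were seen and that changes which alternatives stand out. Positions counted once, with 6 higher, stood out in both units. Standing out only as counts were 154 higher of 1057 without extension, 46 lower of 1508 near annotated ends and 33 lower of 1260 in windows within 2 nt. The main counts were 315 higher and 72 lower of 2009. No read minimum, with 73 lower, stood out only as a share. TMM gave 7 genes lower at 4-fold and 6.17% at 2-fold, median of ratios 7 and 5.97%. No downstream extension gave 49 higher and 8 lower at 4-fold over 1057 measured genes. All values without extension in this section also lack reads in the last 10 nt of each gene, which the shift check removed. Reads near annotated ends gave 2 lower at 4-fold; no read minimum gave 2.296% lower at 2-fold over 3179 genes. A minimum of 50 reads gave 633 clusters higher at 4-fold, and 1502 higher and 609 lower at 2-fold. Distal shifts were 20 with at least 50 reads in each library, 85 at 10 points, 10 at 40 points and 4 at sites near annotated ends, and proximal shifts were 35 with 50 reads, 22 at 40 points, 25 past the stop codon, 37 with sites in introns left out and 2 near annotated ends. Genes with 2 or more sites were 49.6% in input without thinning, and 30.7% in input and 36.4% in sorted nuclei at a 10% minimum. Among 118 named genes, 846 of 1169 values under alternatives stayed within the counting interval, 312 left it and 11 were reversed, meaning that the 2 intervals lay on opposite sides of 1 or that a gene called at 2-fold changed sign. By sign alone, 64 values of 34 genes fell on the other side of a ratio of 1. The first kind were rpl-24.1 at 0.087 in windows within 2 nt, rps-28 at 0.71 without extension, rpl-15 at -0.50 with positions counted once, cpr-5 at -0.061 and -0.051 under TMM and median of ratios, and, near annotated ends, bet-1 at 1.76 and Y54E10A.10 at -0.92 (log2). The second kind were clec-85 at -0.034, col-101 at 0.19 and col-103 at 0.051 with positions counted once and Y71F9B.9 at -0.29 without extension. In simulated data at 1 depth 18 of 50 genes 8-fold lower were called, against 50 of 50 higher.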

Other observations

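The tests on gene families, on coding-sequence reads and with sites in introns left out were chosen after the result was seen. Those with reads near annotated ends, the thinned input, sites past the stop codon and without the largest clusters were chosen after the main counts were seen but before their own results. How the intron share and the sites past the stop codon were judged was settled after their values were seen, and both judgements depart from the bound written for them. Families of genes that stood out among the highest ratios were examined by prefix, 7 in all. The 15 measured genes of the math prefix, which encode MATH-domain proteins, had a median log2 ratio of 3.61, with 14 at least 2-fold higher in sorted nuclei and 0 lower, or 12 higher under TMM and median of ratios. The 16 F-box genes of the fbxa prefix had a median of 2.48, with 11 higher and 0 lower, or 11 and 1 under these scalings, among them fbxa-182 at 6.48 (5.65 to 7.47) and fbxa-54 at 11.7 (9.03 to 15.5). The 5 pals genes, of which pals-22 and pals-25 are known regulators of the response to intracellular pathogens, had a median of 2.38, with 4 higher, or 2 under these scalings. Genes of the bath and btb prefixes had a median of -0.021 over 10 (percentile 26.965), with 2 higher and 1 lower. Of the 5 bath genes, which also encode MATH domains, bath-26 was called higher at 5.70 (3.70 to 8.97) and 4 were not called, from bath-24 at 0.730 to bath-21 at 1.32. Transthyretin-like genes had a median of 0.43 over 3 (percentile 68.3, 1 higher and 1 lower), serpentine receptors of 1.84 over 3 (percentile 92.1, 1 higher) and solute carriers of 1.00 over 2 (0 called). A hypothesis is that genes of the math, fbxa and pals prefixes as groups may be higher in these sorted nuclei. The lowest percentile of the 3 families among 10000 matched random lists was 99.6, but the families were picked from their highest members, many lie close together on the chromosomes, and members are similar in sequence, so they are neither an independent test nor independent genes.

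More genes were 4-fold higher than 4-fold lower in sorted nuclei, 106 against 4. These genes came only from windows toward the start of each chromosome. Clusters on all nuclear chromosomes, scaled to all nuclear reads, split less unevenly, with 982 (6.53%) higher and 164 (1.09%) lower. How far the location of the windows shaped the split of genes was not tested. Scattered background in the sorted library is argued against, since 83 genes were still higher with only reads within 24 nt of an annotated 3' end. Lower depth of the sorted library is argued against as the whole cause, since with the input thinned to the same gene reads 4 genes were lower and 84 higher. Nuclear RNA in the sorted and total RNA in the input library cannot be told apart from the sort itself, because the label follows the group: the intron share was higher by 0.342 points, under the 1 point named beforehand and so against this explanation by that bound, which on seeing the value was judged too wide for a share of 1.22% (1.20 to 1.24) in input against 1.56% (1.53 to 1.59) in sorted nuclei, and retention of spliced transcripts in the nucleus need not show in introns. A difference in tissue between sorted and mixed nuclei, which the design names, stays open and was not tested apart from it.

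The X chromosome held a larger share of reads in sorted nuclei. A few abundant positions are argued against, since without the 100 largest clusters the X share was 12.7% in input and 15.1% in sorted nuclei, a difference of 2.39 points. By distinct positions the shares were 13.1% and 14.6%. The gain was not particular to X: without the 100 largest clusters V went from 18.7% to 20.8%, and 9.47% of its clusters were at least 4-fold higher, against 7.46% on X. A difference in tissue and the RNA label both stay open, untested.

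Proximal shifts outnumbered distal shifts, 77 to 48. Counting error of independent reads is argued against for the number of shifted genes, 125, since it gave at most 8 in 100 draws. The draws did not record direction and took PCR reads as independent molecules, so they do not decide the split of 77 to 48. With only sites past the stop codon there were 0.758 proximal shifts per distal shift, which by the bound named beforehand speaks for internal priming, but the tests that follow leave this undecided. Internal priming in coding sequence is argued against, since its share of gene reads was lower in sorted nuclei, by -0.099 points, and 13 of its 18 shifted sites lost share. The proximal majority rests on sites in introns, without which there were 0.771 proximal shifts per distal shift. Whether these sites are internal priming on unspliced transcripts or true polyA sites cannot be told apart without the sequence at each site. Only protein-coding gene models were used, so the sites were not compared with other annotated genes.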
